A study of Mus musculus with 4 samples.

How the data were processed

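RNA sequencing of liver tissue was analysed for 4 libraries, 2 from wild type mice and 2 from mice with a synonymous Foxo1 mutation. Per the labels, RNA was extracted with TRIzol, mRNA was isolated with Dynabeads, and about 100 ng of mRNA went into libraries made with an Illumina TruSeq RNA kit, a kit that does not mark strand. Sequencing was paired, with reads of 150 bp. The deposited values are raw read counts per Ensembl gene, 1 file per library, not normalised and not pooled by the authors. Reads were aligned with TopHat2 2.1.1 to mm10 and counted with HTSeq 0.6.0, per the submitters' processing notes. The counting mode, the strand setting, the treatment of reads with several placements and the annotation release are not given in the sources used here. For this reason levels of genes with near-identical copies are uncertain, and exon overlaps of named genes are given beside them.

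Each file held 37315 gene rows and no summary rows, so nothing was removed from the library sizes. A symbol was found for 35449 identifiers (95.0%). Coordinates and exon overlaps come from the GENCODE annotation of the mouse genome build that matches mm10. Total counts ranged from 73551737 to 95908652 per library, so a floor of 3 counts stands for 0.0313 to 0.0408 CPM and covers counting error only. Every pair of libraries differed by far more than sampling noise (chi-square per gene of 61.7 to 106), so no 2 libraries were treated as 1. The first principal component of log2 CPM held 38.1% of the variance and separated the groups, and the second held 31.5% and separated the wild type libraries (30.8 and −26.7). Among the tested genes the groups did not overlap in 34.1%, close to the 33.3% that chance alone would give. Wild type replicate 1 was nearer to both mutant libraries (chi-square per gene of 62.5 and 64.3) than to wild type replicate 2 (74.0), whereas its correlation of log2 CPM was higher with the latter (0.988) than with the mutant libraries (0.987 and 0.986).

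Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM (factors of 0.983 to 1.02), and tested with glmQLFit and glmQLFTest with robust estimation, with the group as the only term. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. Of 23104 genes with a count above 0, 14657 were tested. The biological coefficient of variation was 13.1% and the median SE of a log2 fold change 0.15. Standard errors are the absolute log2 fold change over the root of the F statistic. At an unadjusted p below 0.05 there were 907 genes, where chance alone would give a share of 0.05 of the 14657 tested.

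Before the data were examined, 41 gene lists of liver metabolism, signalling, stress, and cell types of liver and neighbouring organs were fixed, with 857 genes, of which 854 were in the files and 777 were tested. Lists with at least 5 tested genes, 37 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count of 2) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. An estimated correlation, and the self-contained fry test, were alternatives. Both rest on the 2 residual degrees of freedom of the fit and have little power, so a call they miss decides little. The lists come from general knowledge, not from these libraries, and some share members. The rule for named genes, fixed at the same time, took Foxo1; the 10 largest rises and falls among genes past the threshold with an average log2 CPM of at least 2 and groups that do not overlap, leaving out symbols of predicted genes; in each list up to 4 members past the threshold; up to 2 of highest expression in a list with none; and Igfbp1, G6pc, Pck1 and Irs2. Of the 50 genes past the threshold, 3 had no established symbol and are counted but not named. Some genes that the rule takes are not reported here.

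Alternatives fixed beforehand were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, the replicate number as a block, each library left out in turn, an adjusted p of 0.1, and a log2 fold change of at least 1. Thinning to the smallest total and removal of a trend on GC content and transcript length were chosen after the data were seen. With 1 library left out, the lone library of a group is assumed to vary like the pair in the other group.

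The test was run on simulated data, 10 sets of 14657 genes drawn from the means and sizes of these libraries with 200 genes changed. With dispersions scattered at random around the fitted trend, 61.0% of 2-fold and 14.4% of 1.5-fold changes were recovered and 8.83% of calls were false. With the gene-wise dispersions of these libraries, 65.2% and 29.3% were recovered and 20.0% of calls were false. Both shares of false calls were above the nominal rate of 0.05. In a simulation of lists, 2 lists shifted 1.3-fold were recovered and 0 of the others among 37 were called. It drew each gene independently, so it could not show false calls that come from correlated genes. In the real libraries the estimated correlation ranged from −0.10 in the cholangiocyte list to 0.77 in the cholesterol list. It was 0.50 in the macrophage list.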

Results

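Gene expression was measured by RNA sequencing of liver from 23-week-old C57BL/6 mice in 2 groups, wild type animals and animals carrying a synonymous mutation of Foxo1, with 2 libraries in each group. A synonymous mutation changes the coding sequence without changing the amino acid. Its position, the base exchanged and the feeding state of the mice are not given in the sources used here. Foxo1 is a forkhead transcription factor that is restrained by insulin and activates gluconeogenic genes in hepatocytes. The deposited counts summed to 80975687 and 73551737 in wild type replicates 1 and 2, and to 95908652 and 83594287 in mutant replicates 1 and 2. Between 18912 and 19578 genes had a count above 0 in a library. Albumin took 7.32% and 7.93% of the counts in the wild type libraries and 6.74% and 6.48% in the mutant libraries, and mitochondrially encoded transcripts took 12.7% to 13.4% in all 4. The male-specific transcript Ddx3y was at 47.0 to 56.6 CPM (counts scaled by library size) in the 4 libraries, and Xist, whose exons overlap those of Tsix and 4 other genes, at 0.0359 to 0.294 CPM. Unless stated otherwise, values are normalised CPM, mean ± SD over the 2 libraries of a group (n = 2), and log2 fold changes are mutant over wild type. The labels do not say that the libraries came from separate animals. The p-values of single genes therefore measure the spread between these samples, which may be technical. The camera p-values at the preset correlation compare genes inside a list with genes outside it. They rest on the spread over genes and treat the members of a list as nearly independent.

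The comparison of mutant with wild type liver asked how expression of Foxo1 and of other genes differed with the synonymous mutation. Foxo1 itself (ENSMUSG00000044167, mm10 chromosome 3, 52268336 to 52353221, plus strand) was at 49.4 ± 7.67 CPM in wild type and 43.5 ± 13.95 CPM in mutant liver. Its log2 fold change of −0.18 had an SE of 0.30, a 95% confidence interval of −1.11 to 0.74 and an edgeR adjusted p of 1.0, so the difference was smaller than the spread between replicates. The mutant libraries held 33.6 and 53.4 CPM of Foxo1 and the wild type libraries 44.0 and 54.8 CPM. Without mutant replicate 1 the log2 fold change was 0.11, and without mutant replicate 2 it was −0.56. Exons of the opposite-strand gene Gm20402 overlap those of Foxo1, and the library kit does not mark strand, so reads there could not be assigned by strand. The related factors Foxo3 and Foxo4 were at 40.6 ± 0.309 and 24.5 ± 1.59 CPM in wild type and 35.5 ± 5.603 and 26.0 ± 0.597 CPM in mutant liver. Neither passed the threshold (edgeR adjusted p of 0.929 and 1.0).

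Classical hepatic targets of Foxo1 did not pass the threshold of an adjusted p below 0.05. G6pc, the catalytic subunit of glucose-6-phosphatase, was at 567 ± 13.5 CPM in wild type and 449 ± 97.1 CPM in mutant liver (log2 fold change −0.34, SE 0.14, edgeR adjusted p = 0.741). Pck1, which encodes phosphoenolpyruvate carboxykinase, was at 2887 ± 514 and 2753 ± 198 CPM, with a log2 fold change of −0.07 and an SE of 0.13. Igfbp1, an insulin-repressed secreted protein, was at 92.1 ± 9.16 and 82.0 ± 21.9 CPM, and the insulin receptor substrate Irs2 at 9.996 ± 1.16 and 9.16 ± 1.17 CPM. Their log2 fold changes were −0.17 (SE 0.20) and −0.13 (SE 0.14), and exons of Irs2 overlap 9530052E02Rik on the opposite strand. Of the 27 measured members of the Foxo1 target list, 9 had a positive and 18 a negative log2 fold change and 0 passed the threshold in edgeR, over all genes or adjusted over the list alone. At an unadjusted p below 0.05 there were 6, with DESeq2 1 and with limma-voom 0. Its median log2 fold change was −0.07 (camera adjusted p = 0.105), and with a filter of 1 CPM in 2 libraries the list was called lower (camera adjusted p = 0.0486). The gluconeogenesis list had a median of −0.03 over 14 genes (camera adjusted p = 0.670), with 0 members past the threshold in edgeR, DESeq2 or limma-voom and 1 at an unadjusted p below 0.05. The sign of Pck1 turned without wild type replicate 1 (0.13) and without mutant replicate 1 (0.0028), and that of Igfbp1 without mutant replicate 1 (0.08).

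**Figure D1:**
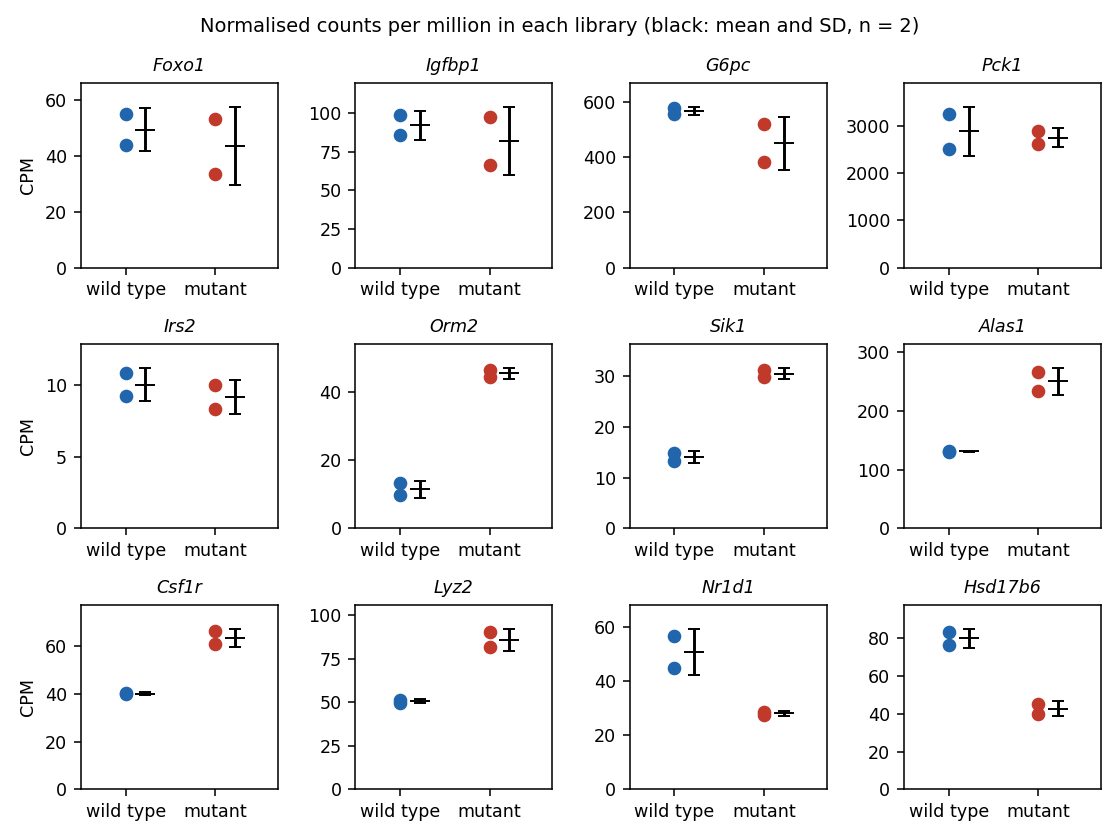
Normalised CPM of 12 genes in each library, with wild type in blue and mutant in red, and the mean and SD of the 2 libraries in black. Foxo1, Igfbp1, Pck1 and Irs2 overlapped between the groups, whereas both mutant libraries lay above both wild type libraries for Orm2, Sik1, Alas1, Csf1r and Lyz2, and below them for G6pc, Nr1d1 and Hsd17b6.

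Across 14657 genes tested, 50 passed the threshold, of which 41 were higher and 9 lower in mutant liver (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The log2 fold change of smallest size among the 50 was 0.50. The largest named rise was in Orm2 (ENSMUSG00000061540, mm10 chromosome 4, 63362449 to 63365878), an acute phase plasma protein, which went from 11.5 ± 2.53 to 45.6 ± 1.601 CPM (log2 fold change 1.99, SE 0.14, edgeR adjusted p = 0.0011). It has close paralogs, Orm1 and Orm3, so its share of their reads is uncertain. Sik1, a salt-inducible kinase induced by cAMP signalling, rose from 14.05 ± 1.16 to 30.5 ± 1.08 CPM (1.12, SE 0.11, edgeR adjusted p = 0.0011). Alas1, the rate-limiting enzyme of haem synthesis in liver, rose from 131 ± 0.432 to 250 ± 22.8 CPM (0.93, SE 0.10, edgeR adjusted p = 0.00228). The liver-secreted protein Fgl1 rose from 167 ± 22.6 to 314 ± 39.2 CPM, with a log2 fold change of 0.91 (SE 0.12, edgeR adjusted p = 0.0109). Mmd2, Tspyl4, Insc and Slc15a3 rose with log2 fold changes of 1.29, 1.10, 0.96 and 0.89. Mup16 went from 416 ± 73.1 to 1006 ± 208 CPM (1.27), but belongs to the major urinary protein family, whose near-identical copies share reads, and is uncertain. Alas1, Tspyl4 and Slc15a3 overlap exons of opposite-strand genes, 4930500F10Rik, Gm47512 and Tmem132a.

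Only 8 of the genes that fell met the criteria for being named. Rgs16, a regulator of G protein signalling (ENSMUSG00000026475, mm10 chromosome 1, 153740349 to 153745468), fell 5.74-fold, from 7.12 ± 0.711 to 1.25 ± 0.454 CPM (log2 fold change −2.52, SE 0.24, edgeR adjusted p = 0.00221). Hsd17b6, a hydroxysteroid dehydrogenase and a member of the periportal list, fell from 79.98 ± 5.07 to 42.6 ± 3.93 CPM (−0.91, SE 0.10, edgeR adjusted p = 0.00228). The nuclear receptor Nr1d1 (REV-ERB alpha), a repressor of the circadian clock, fell from 50.9 ± 8.51 to 28.1 ± 0.830 CPM (−0.86, SE 0.11, edgeR adjusted p = 0.0109). It overlaps exons of Thra on the opposite strand. The X-linked gene Xlr3a fell with a log2 fold change of −1.07 and is uncertain because of close paralogs. The phosphatidylcholine transfer protein Pctp, the inositol hexakisphosphate kinase Ip6k2, the mitochondrial carrier Slc25a47 and the retinol dehydrogenase Rdh16 fell with log2 fold changes of −0.56, −0.64, −0.55 and −0.51. Exons of Rgs16 overlap Gm28513 on the opposite strand, and those of Rdh16 and Slc25a47 overlap Rdh18-ps and Mir345 on the same strand.

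**Figure D2:**
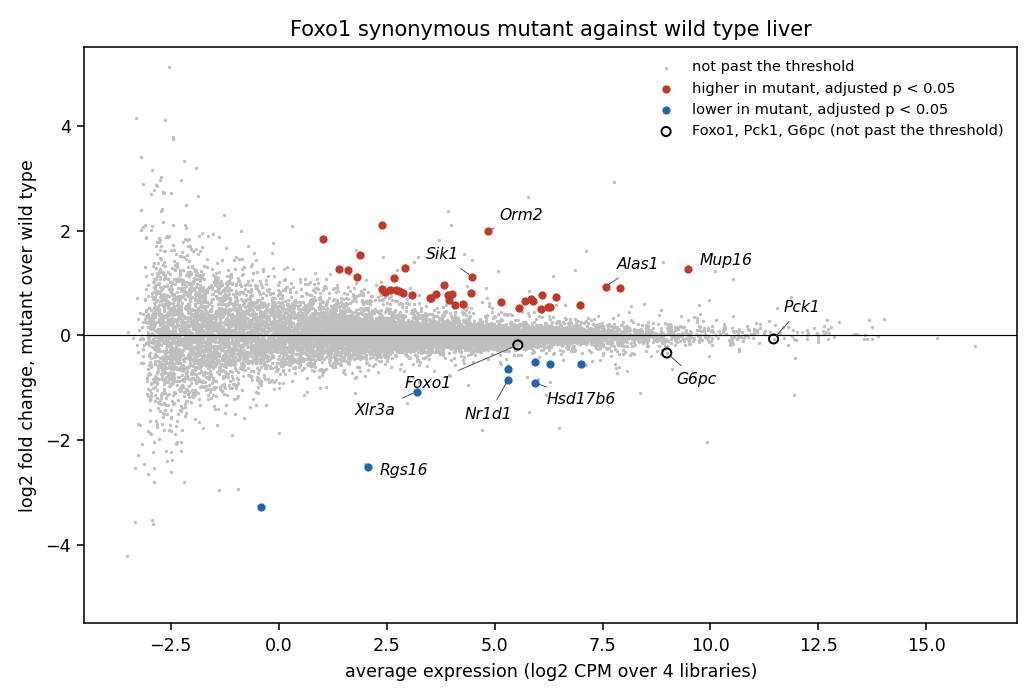
Log2 fold change of mutant over wild type against average log2 CPM over the 4 libraries, for each of the 14657 tested genes. The 41 genes past the threshold that were higher in mutant liver are red and the 9 that were lower are blue. Open circles mark Foxo1, Pck1 and G6pc, which did not pass the threshold, at −0.18, −0.07 and −0.34.

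The number of genes past the threshold depended on the libraries and the test. It was 13 without wild type replicate 1, 17 without wild type replicate 2, 3 without mutant replicate 1 and 15 without mutant replicate 2, and of the 50 genes 4, 7, 0 and 7 passed again. DESeq2 gave 109 genes, limma-voom 7, edgeR without robust estimation 8, and edgeR with a GC and length trend removed 18.

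Markers of Kupffer cells, the resident macrophages of the liver, rose in mutant liver. Of 20 measured members, 7 rose past the threshold over all genes (17 adjusted over the list alone), and 19 had a positive log2 fold change, with a median of 0.64 (camera adjusted p = 3.36e-14). With an estimated correlation the list was not called (camera adjusted p = 0.780). The member with a negative log2 fold change was Gpnmb, at 0.235 ± 0.0774 CPM in wild type and 0.0958 ± 0.0167 CPM in mutant liver. DESeq2 called 14 of its members and limma-voom 1. Lysozyme (Lyz2) rose from 50.6 ± 1.17 to 86.0 ± 6.26 CPM and Csf1r, the receptor for macrophage colony-stimulating factor, from 40.2 ± 0.526 to 63.6 ± 3.71 CPM. Cybb, a subunit of the phagocyte NADPH oxidase, rose from 11.04 ± 0.509 to 18.95 ± 0.315 CPM and the secreted macrophage protein Cd5l from 64.6 ± 4.49 to 108 ± 16.4 CPM. The log2 fold changes of these genes were 0.76, 0.66, 0.78 and 0.74, with edgeR adjusted p of 0.00509, 0.0109, 0.0109 and 0.0226. Exons of Csf1r overlap those of the opposite-strand gene Hmgxb3.

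Medians differed among the lists for other cells found in liver, and the camera test does not compare 1 list with another. Sinusoidal endothelial markers had a median log2 fold change of −0.03 over 19 genes (camera adjusted p = 0.610), stellate cell and fibrosis markers −0.07 over 19 genes (0.359), and cholangiocyte markers −0.06 over 10 genes (0.336). Hepatocyte markers had a median of 0.06 over 20 genes (camera adjusted p = 0.610). In these 4 lists 0 members passed the threshold in edgeR, DESeq2 or limma-voom, with 2, 5, 0 and 0 at an unadjusted p below 0.05. Erythroid and blood markers rose as a list, with 9 of 9 genes positive, a median of 0.54 and a camera adjusted p of 0.000654 (adjusted p = 0.780 with an estimated correlation). Its member Hbb-bt, a beta globin with a close paralog, rose from 9.14 ± 0.615 to 15.9 ± 0.483 CPM (edgeR adjusted p = 0.0145). Lymphocyte markers had a median of 0.30 over 21 genes, 13 positive and 8 negative, with a camera adjusted p of 0.0276 (adjusted p = 0.864 with an estimated correlation). This call was lost with no filter (camera adjusted p = 0.0630) and with a filter of 1 CPM in 2 libraries, where the direction was down (0.657). Among them the pan-leukocyte gene Ptprc rose from 6.30 ± 0.353 to 10.8 ± 0.883 CPM (edgeR adjusted p = 0.0405), whereas Ighm was at 11.2 ± 6.98 in wild type and 4.55 ± 2.04 CPM in mutant liver. Neutrophil markers had a median of 0.95 over 5 genes, with a camera adjusted p of 0.0276 (adjusted p = 0.780 with an estimated correlation), and the group means of all 5 were below 3 CPM. With no filter the neutrophil list was not called (camera adjusted p = 0.182). Without wild type replicate 1 or without mutant replicate 1 the lymphocyte list had a camera adjusted p of 0.891 and 0.746, and the neutrophil list 0.0950 and 0.158. Without wild type replicate 1 the medians of the lymphocyte, neutrophil and erythroid lists were −0.05, 0.22 and 0.23, against 0.52 for the macrophage list. Without wild type replicate 2 they were 0.61, 1.22 and 0.73, against 0.75. Without mutant replicate 1 they were 0.36, 0.86 and 0.40, against 0.78, and without mutant replicate 2 0.30, 0.92 and 0.46, against 0.52. MHC class II genes were not called, with a median of 0.38 over 8 genes (camera adjusted p = 0.452), and their median ranged from −0.06 without mutant replicate 2 to 0.79 without wild type replicate 2.

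Acute phase response genes, which encode plasma proteins and stress proteins induced in inflammation, rose as a list. Of 28 measured members 26 had a positive log2 fold change, with a median of 0.29 (camera adjusted p = 1.31e-08, and adjusted p = 0.780 with an estimated correlation). Orm2 and Apcs rose past the threshold over all genes, and 5 members did so adjusted over the list alone. Apcs, serum amyloid P, rose from 63.7 ± 3.13 to 92.8 ± 4.59 CPM (log2 fold change 0.54, SE 0.09, edgeR adjusted p = 0.0312). The other 3, chosen after their values were seen, were Hpx, Orm1 and Socs3, with log2 fold changes of 0.52, 0.48 and 0.88 and edgeR adjusted p over all genes of 0.174, 0.181 and 0.181. Macrophage and blood markers were higher in the same libraries, with list medians of 0.64 and 0.54.

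The lists of fatty acid oxidation and of fatty acid and triglyceride synthesis fell, with 0 members past the threshold over all genes in edgeR. DESeq2 called 4 members of the oxidation list and 1 of the synthesis list, limma-voom 0 of both, and 11 and 3 had an unadjusted p below 0.05 in edgeR. Of 32 measured genes of fatty acid oxidation and PPAR alpha response, 31 had a negative log2 fold change, with a median of −0.25 (camera adjusted p = 4.95e-08, and adjusted p = 0.805 with an estimated correlation). Without wild type replicate 1 the median of the list was −0.13, and the list was still called (camera adjusted p = 0.0211). Adjusted over the list alone, 4 members passed in edgeR, namely Acaa1b, Ehhadh, Fabp1 and Acot1, with log2 fold changes of −0.69, −0.55, −0.39 and −0.87; they are named after their values were seen. Of 21 genes of fatty acid and triglyceride synthesis, all 21 had a negative log2 fold change, with a median of −0.33 (camera adjusted p = 2.13e-05, and adjusted p = 0.864 with an estimated correlation). Scd1, the delta-9 desaturase, was at 5373 ± 1924 CPM in wild type and 2430 ± 171 CPM in mutant liver (edgeR adjusted p = 0.589), and the carbohydrate-responsive factor Mlxipl at 396 ± 11.8 and 347 ± 68.7 CPM. Adjusted over the list alone 2 members passed, Me1 (−0.47) and Elovl6 (−0.38), also named after their values were seen. Acaa1b, Me1, Elovl6 and Mlxipl overlap exons of opposite-strand genes, Dlec1, A330041J22Rik, Gm35986 and Gm43500. Without wild type replicate 2 the synthesis list was no longer called (camera adjusted p = 0.247) and its median was −0.06, against −0.63 without wild type replicate 1. Genes of cholesterol synthesis and uptake had a median of 0.10 over 24 genes (camera adjusted p = 0.619). That median was −0.23 without mutant replicate 1 and −0.07 without wild type replicate 1, and the list was called higher without wild type replicate 2 (median 0.27, camera adjusted p = 0.0171) and without mutant replicate 2 (0.25, 0.00178).

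**Figure D3:**
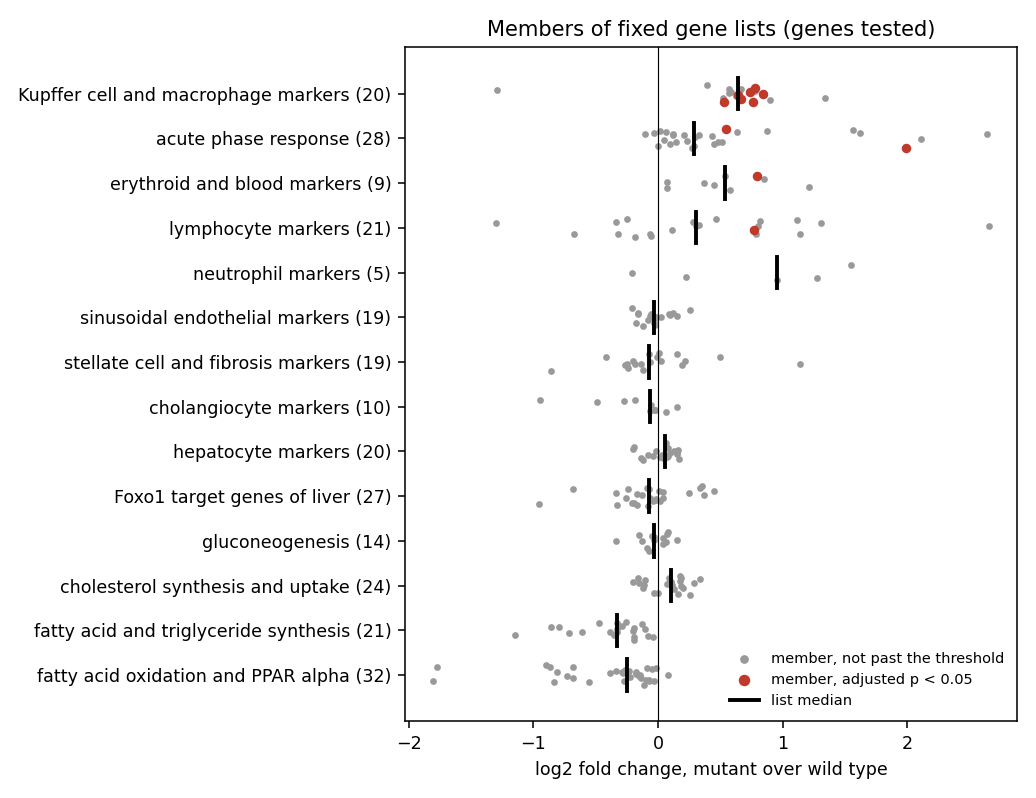
Log2 fold changes, mutant over wild type, of the measured members of 14 gene lists, with red points past the threshold over all genes, grey points not past it, and black bars at list medians. The macrophage list sits furthest above 0 among lists of 20 or more genes, with a median of 0.64, while endothelial, stellate, cholangiocyte and hepatocyte lists have medians of −0.03, −0.07, −0.06 and 0.06.

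Circadian clock genes moved up as a list although Nr1d1, the only member past the threshold over all genes, fell. Of 20 members 15 had a positive log2 fold change, with a median of 0.14 (camera adjusted p = 0.0173, and adjusted p = 0.780 with an estimated correlation). Adjusted over the list alone, Nr1d1 fell and 2 members rose, the clock-controlled genes Ciart (1.08, SE 0.30) and Usp2 (0.77, SE 0.21), named after their values were seen. Exons of Usp2 overlap Gm39325 and Gm49380 on the opposite strand. The list was not called without mutant replicate 1 (camera adjusted p = 0.110), without mutant replicate 2 (0.0736) or with no filter (0.0606). Heat shock genes, interferon response genes and cytosolic ribosomal proteins had medians of 0.16, 0.08 and 0.08 over 15, 31 and 50 genes, with camera adjusted p of 0.0173, 0.0276 and 0.0276. With an estimated correlation the adjusted p was 0.864 for each, and 0 of their members passed the threshold over all genes in edgeR, DESeq2 or limma-voom, with 3, 6 and 1 at an unadjusted p below 0.05. The heat shock list was lost without wild type replicate 2 (camera adjusted p = 0.276) and mutant replicate 1 (0.392), and the interferon list without wild type replicate 1 (0.891) and mutant replicate 1 (0.392). The ribosomal list was called without wild type replicate 2 (camera adjusted p = 0.000907) but not without wild type replicate 1 (0.979), mutant replicate 1 (0.110) or mutant replicate 2 (0.195). With no filter the interferon and ribosomal lists were not called (camera adjusted p of 0.0888 and 0.111). Leaving out 1 library gave medians of 0.043 to 0.320 for the heat shock list. For the interferon and ribosomal lists they ranged from 0.015 to 0.146 and from 0.00061 to 0.122.

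Of the 37 lists tested, 9 were called higher and 2 lower, and the other 26 were not called. With an estimated correlation, or with the fry test, 0 lists were called in either direction. Both rest on 2 residual degrees of freedom, so they could hardly call a list. The clock list had an estimated correlation of −0.04, below the preset 0.01, yet its unadjusted camera p rose from 0.00321 to 0.0847. A call lost in this way therefore need not come from correlated members. Glycolysis and glycogen genes had a median log2 fold change of −0.05 (camera adjusted p = 0.0785), insulin and glucagon signalling −0.02 (0.528), xenobiotic metabolism −0.08 (0.359), apolipoproteins −0.06 (0.573), and nuclear genes of oxidative phosphorylation −0.01 (0.573). Endoplasmic reticulum stress genes had a median of 0.15 (camera adjusted p = 0.105), immediate early genes 0.21 (0.189), and female-biased and male-biased liver genes 0.28 (0.273) and 0.13 (0.162). With 1 library left out some of these lists were called. Endoplasmic reticulum stress genes were called higher without wild type replicate 1 (camera adjusted p = 0.0102) and without mutant replicate 2 (0.00179), but had a median of −0.02 without mutant replicate 1. Immediate early and female-biased genes were called higher without wild type replicate 2 (camera adjusted p of 0.00866 and 0.0488), male-biased genes higher without wild type replicate 1 (0.00624), and insulin and glucagon signalling lower without mutant replicate 2 (0.0371). The m6A RNA modification machinery had a median of −0.05 (camera adjusted p = 0.603), mitochondrially encoded transcripts −0.01 (0.610), p53 targets 0.02 (0.734), and periportal genes −0.02 (0.809). Bile acid transport and amino acid catabolism were not called either (camera adjusted p of 0.692 and 0.763). In the cell cycle and adipose lists, the median (0.10 and 0.10) and mean were positive while the direction of camera was down (adjusted p of 0.983 and 0.983). In the pericentral list the median was 0.03 and the mean −0.0021, with camera up (adjusted p = 0.782). Too few genes for a test were measured in the Foxo family, pancreas, kidney and gut, and skeletal muscle lists, with 3, 3, 3 and 1.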

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

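Thinning and the GC and length trend were chosen after the data were seen. The 50 genes past the threshold (41 higher, 9 lower) kept their direction in each alternative run. This held for 49 of 49 with a filter of 1 CPM in 2 libraries and 50 of 50 elsewhere. The groups did not overlap for any of the 50, so leaving out 1 library could hardly turn a direction and does not test it. RLE and upper-quartile scaling and thinning to the smallest total gave 50, 50 and 47 genes. Higher and lower genes numbered 197 and 61 with no filter, 21 and 3 with the 1 CPM filter, 82 and 27 with DESeq2, 5 and 2 with limma-voom, 6 and 2 without robust estimation, 13 and 5 with the trend removed, and 11 and 3 at a log2 fold change of at least 1. At an adjusted p of 0.1, 16 were lower. With 1 library left out, higher genes ranged from 2 (without mutant replicate 1) to 10 and lower genes from 1 to 7, with fewer samples as part of the cause. Apart from those fits, the cause was not tested.

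The log2 fold change of Foxo1 ranged from −0.56 to 0.11 with 1 library left out, reversing without mutant replicate 1, and from −0.21 to −0.18 in the other alternatives, with no call in any. With 1 library left out Pck1 ranged from −0.24 to 0.13, reversing without wild type replicate 1 (0.13) and mutant replicate 1 (0.0028), and Igfbp1 ranged from −0.47 to 0.082, reversing without mutant replicate 1.

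Lists called higher (9) and lower (2) numbered 4 and 2 with no filter, 0 and 0 with an estimated correlation, 0 and 0 with fry, 3 to 11 and 1 to 3 with 1 library left out. The macrophage, acute phase, fatty acid oxidation and erythroid lists were called in all 4 of the latter, at highest camera adjusted p of 1.54e-08, 4.40e-05, 0.0211 and 0.0442. With no filter the clock, lymphocyte, interferon, ribosomal and neutrophil lists were lost (camera adjusted p of 0.0606, 0.0630, 0.0888, 0.111 and 0.182). With the 1 CPM filter the lymphocyte list turned down (camera adjusted p = 0.657) and the Foxo1 target list, not called otherwise, was called lower (0.0486).

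The replicate numbers occur in both groups, but the labels state no batch and no pairing. Over all genes the correlation of replicate deviations was −0.0072. With 2 pairs this cannot exclude a shared batch that acts on part of the genes. With the replicate number as a block, 83 genes were higher and 28 lower, 49 of them among the 50, and Foxo1 was at −0.21. The block called the MHC class II and endoplasmic reticulum stress lists higher (camera adjusted p of 0.00982 and 0.00982) and lost the cytosolic ribosomal protein list (0.0558).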

Other observations

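The test of linked passenger variants, the thinning and the GC and length correction, and the gene families outside the fixed lists were chosen after the results were seen.

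Gene groups other than the fixed lists are described by their members, with no test of a group. Some of these genes are also members of a fixed list. Among genes past the threshold that are known for expression in leukocytes, the integrin Itgal rose from 8.60 ± 0.303 to 14.1 ± 0.133 CPM (SD, n = 2, edgeR adjusted p = 0.0312) and properdin, Cfp, from 15.4 ± 0.130 to 23.2 ± 1.49 CPM (0.0405). Alas1 rose, whereas the later enzymes of haem synthesis Alad, Urod and Fech had log2 fold changes of −0.17, −0.03 and −0.03, with edgeR adjusted p of 0.919, 1.0 and 1.0, and Hmox1, which degrades haem, was at 0.44 (0.174). Cish, a cytokine-inducible inhibitor of STAT5 signalling, rose from 1.87 ± 0.0737 to 5.42 ± 1.44 CPM (edgeR adjusted p = 0.0109), while Socs2 was at 4.49 ± 2.87 and 5.13 ± 2.68 CPM and Igf1 at 439 ± 89.9 and 485 ± 17.97 CPM. Other genes that respond to growth hormone or cytokines, Socs3, Onecut1 and Bcl6, had log2 fold changes of 0.88, 1.62 and −0.95, with edgeR adjusted p of 0.181, 0.663 and 0.584. Exons of Cish overlap the opposite-strand genes Gm17040 and Gm17041, those of Bcl6 overlap Gm37419 on the opposite strand, and those of Onecut1 overlap Gm20649 on the same strand. Id3 rose from 11.7 ± 0.537 to 20.3 ± 0.0178 CPM (0.0109), and Id2 was at 58.5 ± 1.97 and 79.1 ± 2.05 CPM (0.0730).

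On the X chromosome all 4 measured Xlr3 and Xlr4 genes, which lie between 73074345 and 73222453, had a negative log2 fold change, of which Xlr3a and Xlr3b fell past the threshold (log2 fold changes of −1.07 and −3.28, edgeR adjusted p of 0.0456 and 0.0135), and their sum was 15.4 ± 0.509 in wild type and 6.24 ± 1.31 CPM in mutant liver. Xlr3b was low, at 0.941 and 1.83 CPM in the wild type and 0.116 and 0.167 CPM in the mutant libraries. The log2 fold changes of Xlr4a and Xlr4b had edgeR adjusted p of 0.629 and 0.966. Xlr4b was at 0.193 and 1.67 CPM in the wild type and 0.210 and 0.0239 CPM in the mutant libraries. These are near-identical copies, how their shared reads were counted is not given in the sources used here, and Xlr3a makes up most of the sum, at 12.4 ± 1.63 CPM in wild type. Of 21 major urinary protein genes 15 had a positive log2 fold change, and their sum was 50764 ± 2429 in wild type and 59167 ± 2093 CPM in mutant liver, a log2 ratio of 0.22, against 1.27 for Mup16 alone. Mup13 stood at 125 and 3005 CPM in the wild type libraries and at 353 and 411 CPM in the mutant libraries. All 6 measured Cyp4a genes had a negative log2 fold change. Of these, Cyp4a10, Cyp4a14 and Cyp4a31 are also members of the fatty acid oxidation list, and Cyp4a12a and Cyp4a12b of the male-biased list. The wild type libraries held 680 and 370 CPM of the 6 genes in sum and the mutant libraries 333 and 294. The spread within wild type was therefore large. The serum amyloid genes Saa1 and Saa2 were at 68.2 ± 24.1 and 15.1 ± 7.33 CPM in wild type and at 209 ± 36.8 and 94.0 ± 28.5 CPM in mutant liver, with edgeR adjusted p of 0.624 and 0.754.

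Macrophage markers rose by a median log2 fold change of 0.64 in mutant liver, with 7 of 20 past the threshold, but were not called as a list with an estimated correlation (camera adjusted p = 0.780) or with fry (adjusted p = 0.302). A lower hepatocyte share would raise the markers of other liver cells alike. Sinusoidal endothelial markers had a median of −0.0288, below the 0.32 that this would need by 0.348, with a bootstrap SE of 0.0349. The bootstrap drew list members, so its SE leaves out the spread between libraries. With 1 library left out the endothelial median ranged from −0.054 to −0.0054, against 0.52 to 0.78 for the macrophage list. A GC or length trend is argued against by a macrophage median of 0.623 after its removal. More residual blood stays open. Lymphocyte, neutrophil and erythroid markers together had a median of 0.448, above the 0.32 that blood would need by 0.128, with a bootstrap SE of 0.162. Without wild type replicate 1 the lymphocyte, neutrophil and erythroid medians were −0.05, 0.22 and 0.23 against 0.52 for macrophages. Without wild type replicate 2 they were 0.61, 1.22 and 0.73 against 0.75. Without mutant replicate 1 they were 0.36, 0.86 and 0.40 against 0.78, and without mutant replicate 2 0.30, 0.92 and 0.46 against 0.52. Hbb-bs was at 79.0 ± 25.0 and 118 ± 13.7 CPM and Ighm at 11.2 ± 6.98 and 4.55 ± 2.04 CPM. Copies of globin genes may be undercounted. None of the 20 macrophage markers belongs to another list, while 6 of 9 erythroid, 5 of 21 lymphocyte and 1 of 5 neutrophil markers were at 1 CPM or more in wild type liver. More Kupffer cells, or higher expression in them, with the Foxo1 mutation is a hypothesis that was not tested further. Blood and a technical difference between the libraries stay open beside it.

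Of the 20 clock genes only Nr1d1 passed the threshold over all genes, and it was lower. Their list was called higher at the preset correlation. It was not called with an estimated correlation (camera adjusted p = 0.780) or with fry (adjusted p = 0.302). If the mutant livers stood at another phase, genes of the morning arm and of the evening arm were predicted to move apart. Their medians of 0.01 and 0.25 differed by −0.237 with a bootstrap SE of 0.160, which leaves a phase difference open. Within the evening arm Nr1d1 fell while Ciart and Usp2 rose, so its median mixes genes that moved in opposite directions. Thinning to the smallest total gave a median absolute log2 fold change of 0.160 over the 20 clock genes, but it moved no clock gene by more than its SE and decides nothing about depth. The times at which the livers were taken and the feeding state of the mice are not given in the sources used here, and a difference tied to the mutation also stays open and untested.

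The 50 genes past the threshold were compared with the other ways of splitting the 4 libraries into 2 and 2. Of the 3 splits 1, the real one, gave as many, and the highest of the others gave 1 gene, but 3 splits are too few for a share below 0.05. Passenger variants linked to Foxo1 would place called genes on chromosome 3, where 2 of the 50 lie against 698 of the 14657 tested (Fisher's exact test, one-sided, p = 0.695). The upper limit of the odds ratio, 3.19, is too high to exclude them, and a biological difference between the groups stays open.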
